A study of Caenorhabditis elegans with 15 samples.

How the data were processed

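Poly-A RNA of sorted, starved L1 larvae was made into libraries with a kit for SOLiD sequencing, per the labels. Embryos were freed by bleaching and hatched without food, larvae were passed through a 27 µm mesh, and the worm sorter took GFP-negative larvae of both array strains in batches of 50000, with sorts usually pooled in pairs. The labels list 15 samples and the count table holds 14 of them; double-mutant replicate 4 was not analysed here, so the fit planned for 15 libraries ran on 14. Sort dates came from the deposited column descriptions.

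The main values are counts of reads per gene, which the authors made with HTSeq (0.6.1), and the genome build was ce10, per the submitters' processing notes. These notes also name SAMtools (1.3.1), FastQC (0.52), DESeq2 and bedtools. The aligner and the strand setting of the counting are not given in the sources used here, so reads of genes whose exons overlap cannot be told apart; of 430 genes named by size, p or list, 67 have an exon that overlaps another annotated gene. The lowest total of a gene over all libraries was 11 reads, and 16708 of the 20447 genes of the deposited annotation (lifted to ce10 by the authors, per its name) are in the table. Gene symbols and coordinates were taken from that annotation, and 807 genes of the count table had no symbol beyond a sequence name. A companion table of regularized log2 values, made by the authors with all 14 libraries per the deposited column descriptions, was used in an added alternative only. Reads shared between near-identical paralogs, such as members of the C-type lectin, MATH, BATH and F-box families, could have been lost or split by the authors' counting, and values of such genes are uncertain.

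Library totals ran from 10737956 to 19071067 counts, so that 1 count was worth between 0.0524 and 0.0931 CPM. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total 15) kept 13700 genes, TMM gave scaling factors of 0.919 to 1.08, and the quasi-likelihood F test was run with all 4 groups in a single fit (common biological coefficient of variation 0.118). The contrasts were elt-2(-), elt-7(-) and the double mutant against wild type, the double mutant against each single mutant, and the interaction. P-values are two-sided, adjusted by Benjamini-Hochberg within each contrast, and called under 0.05. Standard errors are the absolute log2 fold change over the square root of F. Gene lists (32, fixed before the data were examined, each with at least 3 tested members) were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation and with fry. Some genes stand in more than 1 list. Genes with 0 reads in a group got a lower bound from a floor of 3 counts over the group, and genes with 1 to 3 reads a ratio with a 95% exact binomial counting interval. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

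Named genes followed a rule fixed before the data were examined. In each contrast of a pair of groups it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. For the interaction it took the 10 called genes with the smallest p and at least 10 CPM in a group. It added the GATA and endoderm regulators, the 4 members of a list with the smallest p in a contrast, and the 3 most abundant members of the lists of other tissues. Levels of such genes are also given in groups other than those of the contrast that named them, and genes outside the rule are named as chosen after their values were seen.

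The pipeline was tested on simulated data with 50 genes changed at each of 4 fold sizes. For elt-2(-) against wild type (13448 genes) it recovered 52% of genes changed 1.5-fold, 84% at 2-fold and 100% at 4-fold, and called 12 of 13249 unchanged genes. For the interaction (13445 genes) it recovered 22% at 1.5-fold, 68% at 2-fold and 96% at 4-fold. The simulated list changed 1.5-fold was called and 0 of 31 other lists were. Genes were simulated independently of each other, so this does not test false calls of lists whose members vary together. Far fewer genes changed in the simulation than were called in the data. The adjusted threshold was therefore stricter there, and the recovered shares do not carry over to the data. Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no low-count filter, a minimum mean of 5 CPM, the replicate number as a block, fits with the groups of a contrast alone, stricter thresholds, split wild-type controls, and leaving out each library in turn. limma-trend on the deposited log2 values was added after the data were seen. Median log2 changes of all genes exceeded 0.1 in size only without scaling (-0.11 in elt-2(-) and -0.149 in elt-7(-)). With TMM they were -0.0137 and -0.0388.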

Results

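The intestine of the nematode Caenorhabditis elegans depends on GATA-type transcription factors, and ELT-2 and ELT-7 are the pair that stays active in its differentiated cells. The series compares starved first-stage (L1) larvae of 4 genotypes with and without these factors. Poly-A RNA of whole larvae was sequenced from wild type (N2, 4 libraries), an elt-7 mutant carrying the tm840 allele (3 libraries), an elt-2 mutant carrying the ca15 allele (4 libraries) and the elt-7; elt-2 double mutant (3 libraries). Larvae without ELT-2 cannot be kept as a strain, so both elt-2 strains carried an extrachromosomal transgene array with elt-2, a sur-5 promoter driving GFP, and the roller marker rol-6(su1006). Larvae that had lost the array were collected as GFP-negative animals on a worm sorter. Library totals ran from 10737956 counts in elt-7(-) replicate 2 to 19071067 in elt-2(-) replicate 2, and 13700 of 16708 genes passed the low-count filter. Levels in CPM (counts scaled to library size) are given as mean ± SD over these libraries, and log2 fold changes as estimate ± standard error. Adjusted p-values measure the spread between libraries, each pooled from sorted larvae, and the labels do not say whether all replicates came from separate cultures.

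Reads of elt-2 (WBGene00001250, chromosome X, 10481177 to 10483520 in ce10) fell from 29.9 ± 5.10 CPM in wild type to 6.81 ± 1.22 in elt-2(-) and 2.57 ± 0.820 in the double mutant, which left 22.8% and 8.58% of the wild-type mean. The log2 change of elt-2 was -2.15 ± 0.16 in elt-2(-) (adjusted p = 7.68e-09) and -3.51 ± 0.21 in the double mutant (adjusted p = 2.72e-10), and -0.10 ± 0.16 in elt-7(-) (adjusted p = 0.668). Reads of elt-7 (WBGene00015981, chromosome V, 4770657 to 4773077) stood at 14.7 ± 1.39 CPM in wild type and 11.6 ± 1.78 in elt-7(-), a log2 change of -0.35 ± 0.13 that missed the threshold (adjusted p = 0.0558). In elt-2(-) elt-7 rose by 0.62 ± 0.11 (adjusted p = 1.07e-04), and in the double mutant it fell by 0.55 ± 0.13 (adjusted p = 0.00117). The labels do not say which part of either gene the alleles delete, and reads outside a deleted part remain countable, so the elt-7 reads check no label. The array marker rol-6, a cuticle collagen, stood at 0.598 ± 0.203 CPM in wild type, 0.287 ± 0.353 in elt-7(-), 7.20 ± 0.617 in elt-2(-) and 8.36 ± 2.06 in the double mutant. For sur-5 the means were 144 ± 8.78, 107 ± 6.95, 201 ± 8.92 and 191 ± 25.7 CPM in the same order. Reads that carry array sequence or come from array-bearing larvae cannot be separated from endogenous reads in these counts.

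**Figure D1:**
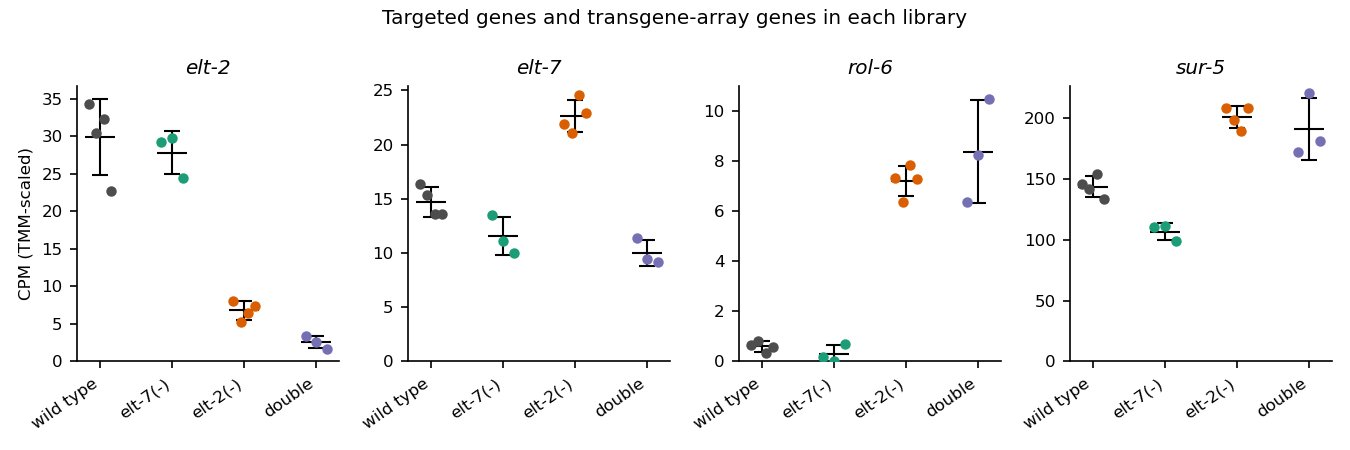
TMM-scaled CPM of elt-2, elt-7, rol-6 and sur-5 in each library (points), with the group mean and SD (bars), for the 4 genotypes. Mean elt-2 CPM was 29.9 in wild type, 6.81 in elt-2(-) and 2.57 in the double mutant, while rol-6 reads were highest in both strains that carried the array.

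Libraries separated by genotype on the first and second principal components. The first principal component of log2 CPM held 61.5% of the variance and set wild type and elt-7(-) apart from elt-2(-) and the double mutant. The second held 20.9% and set elt-2(-) apart from the double mutant. The third held 5.33% and set wild type (14.4 to 24.4) apart from elt-7(-) (-30.3 to -22.2). Double-mutant replicate 3 lay near elt-7(-) on it, at -21.8, but replicates 1 and 2 lay at 20.7 and 11.1. The third component therefore does not follow the state of elt-7 alone. Pearson correlations across genes were 0.984 to 0.989 between wild-type libraries, 0.975 to 0.982 between wild type and elt-7(-), 0.898 to 0.905 between wild type and elt-2(-), and 0.866 to 0.882 between wild type and the double mutant. Genes are not independent replicates, so no p-value goes with these correlations. The share of counts from the 12 mitochondrial genes was 2.53% to 3.05% in wild type, 1.5% to 1.91% in elt-7(-), 0.758% to 1.06% in elt-2(-) and 0.466% to 1.57% in the double mutant. Double-mutant replicate 3 stood apart from its group, with a chi-square per gene of 44.7 and 31.4 against replicates 1 and 2, which differed from each other by 8.08. No pair of replicates was close enough to sampling noise to be 1 library given under different names.

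**Figure D2:**
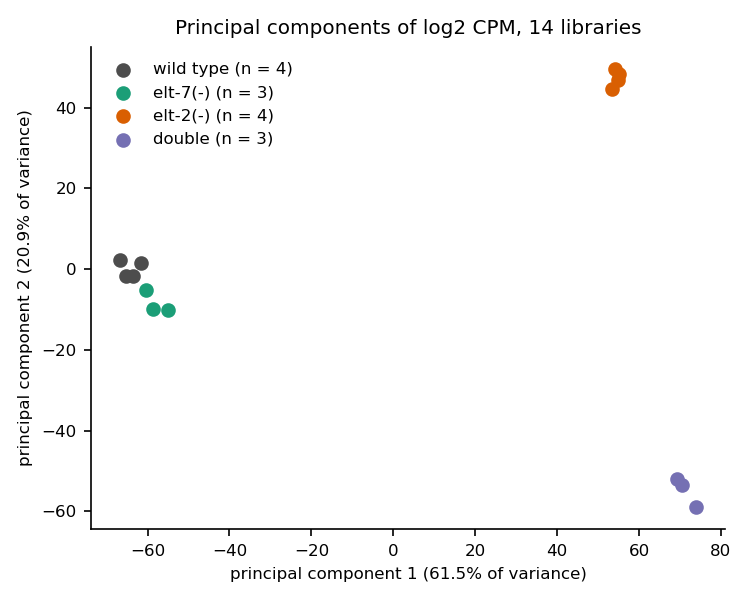
Positions of the 14 libraries on the first and second principal components of log2 CPM, which held 61.5% and 20.9% of the variance, coloured by genotype. Wild-type and elt-7(-) libraries lie at negative values of the first component, elt-2(-) and double-mutant libraries at positive values and apart from each other on the second.

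Loss of ELT-2 with ELT-7 present was read from elt-2(-) against wild type. The largest falls were in genes of different kinds. irg-3, an infection response gene, fell by 6.57 ± 0.20 on the log2 scale (from 159 ± 27.6 to 1.61 ± 0.449 CPM), spp-1, a saposin-like antimicrobial protein gene, fell by 6.57 ± 0.22, and the lysozyme gene ilys-5 fell by 6.10 ± 0.31. The metallothionein gene mtl-2 fell by 6.29 ± 0.23, the acid phosphatase gene pho-11 fell by 6.14 ± 0.18, and the receptor tyrosine kinase gene ver-2 fell by 6.53 ± 0.22. Other genes appeared that wild type hardly expressed. The saposin-like gene spp-21 had 0 reads over the 4 wild-type libraries and 1454 in elt-2(-), at least 457-fold higher against a floor of 3 counts over the group, and the neighbouring genes F16G10.6 and F16G10.7 were at least 407-fold and 399.6-fold higher. delm-2, a degenerin-like ion channel gene, rose by 8.85 ± 0.22 (from 0.497 ± 0.221 to 237 ± 12.2 CPM) and phg-1 by 8.72 ± 0.22. Floors and counting intervals cover counting error only. The adjusted p of these genes ran from 1.36e-14 for delm-2 to 1.14e-09 for F16G10.7.

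Intestinal gene groups moved in both directions in elt-2(-). Among cathepsins and other digestive proteases 10 of 24 tested members rose and 13 fell (10 and 13 adjusted over the list alone), with cpr-6, cpz-2 and asp-2 down, at -4.66 ± 0.11, -4.29 ± 0.11 and -4.65 ± 0.17 and cpr-3 up by 3.79 ± 0.09. The list as a whole was not called (camera adjusted p = 0.145). Of the brush border and lumen genes, 12 of 16 tested members rose and 0 fell (12 and 1 adjusted over the list alone). The median was 0.58 (camera adjusted p = 6.34e-04, and adjusted p = 0.560 with an estimated correlation): the microvillar actin gene act-5 rose by 2.04 ± 0.13, the filament organizer ifo-1 by 1.21 ± 0.10 and the ezrin gene erm-1 by 0.68 ± 0.06. Genes of the vacuolar proton pump went the same way, as 15 of 20 tested members rose and 3 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.00376, and adjusted p = 0.560 with an estimated correlation), among them vha-13 at 1.06 ± 0.08 and vha-1 at 0.71 ± 0.06, while vha-7 fell by 0.83 ± 0.09. Intestinal transporters split: 9 of 20 tested members rose and 7 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.559): the gut-granule transporter genes haf-4 and haf-9 fell, at -4.66 ± 0.15 and -4.44 ± 0.14, and the peptide transporter gene pept-1 rose by 1.71 ± 0.12. Of the heat shock and unfolded-protein genes, 10 of 13 tested members rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.00111, and adjusted p = 0.108 with an estimated correlation). Examples are the Hsp70 gene hsp-1 at 1.36 ± 0.12 and hsp-110 at 0.88 ± 0.07. Among other GATA and endoderm regulators, elt-3 and elt-1, GATA factor genes of the epidermis, fell, at -0.78 ± 0.12 and -0.82 ± 0.12, pha-4, the pharynx regulator, rose by 0.64 ± 0.11, and elt-4, the gene next to elt-2 on X, also fell (adjusted p = 0.00110).

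Markers of other tissues moved as well. In the germline list 18 of 21 tested members rose and 0 fell (18 and 0 adjusted over the list alone). The median was 3.07 (camera adjusted p = 1.43e-07, and adjusted p = 0.108 with an estimated correlation). The P-granule genes pgl-1 and glh-1 rose by 5.26 ± 0.18 and 4.51 ± 0.17, from 0.912 ± 0.418 and 1.32 ± 0.345 to 35.2 ± 2.24 and 30.2 ± 2.54 CPM, and the Argonaute gene csr-1 rose by 2.48 ± 0.10. In the adult and oocyte list 10 of 12 tested members rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 4.72e-04, and adjusted p = 0.260 with an estimated correlation). Examples are the egg surface receptor gene egg-2 at 4.95 ± 0.27 and the yolk receptor gene rme-2 at 3.54 ± 0.20, while the yolk gene vit-6 fell by 1.23 ± 0.50 (adjusted p = 0.0408). Neuronal markers went down: 0 of 28 tested members rose and 22 fell (0 and 22 adjusted over the list alone). The median was -0.58 (camera adjusted p = 4.53e-06, and adjusted p = 0.108 with an estimated correlation). They include the synaptic vesicle gene rab-3 at -0.96 ± 0.07 and the kinesin gene unc-104 at -1.07 ± 0.09. Of the neuropeptide genes 2 of 70 tested members rose and 55 fell (2 and 55 adjusted over the list alone). The median was -0.71 (camera adjusted p = 2.29e-10, and adjusted p = 0.260 with an estimated correlation). They include nlp-15 at -1.35 ± 0.07 and flp-20 at -1.17 ± 0.07. No germline or neuronal list call held with an estimated correlation, and neither did any other list call in the 6 contrasts.

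Across all genes, 8534 of 13700 were called in elt-2(-) at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 4230 higher and 4304 lower, and 2908 of them changed at least 2-fold. Camera called 7 of 32 gene lists. This number rose to 12 without wild-type replicate 2 and to 11 without elt-7(-) replicate 1 or without double-mutant replicate 2, and was also 12 with the replicate number as a block. The state of elt-2 goes together with the array strain and the selection of GFP-negative larvae in every library, while larvae of all 4 genotypes are labelled as sorted. The counting did not come with a stated strand setting, so genes with exons that overlap another annotated gene are uncertain, among those named for this comparison asp-2, cpz-2, pho-11, rab-3, spp-1 and vha-13.

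Loss of ELT-7 with ELT-2 present was read from elt-7(-) against wild type, where genes changed by smaller amounts. This contrast also carries any effect of the later sort period of the elt-7(-) libraries. Among the largest rises, ncl-1, a repressor of nucleolar size, rose by 2.42 ± 0.10 (from 57.1 ± 7.95 to 305 ± 0.932 CPM) and its neighbour on chromosome III, ZK112.3, by 3.28 ± 0.24. The G-protein alpha subunit gene gsa-1 rose by 2.23 ± 0.11, the poly-A binding protein gene pab-2 by 2.10 ± 0.10, the mitochondrial transporter gene abtm-1 by 1.97 ± 0.09, the histone methyltransferase gene set-25 by 1.85 ± 0.14 and the CREB gene crh-1 by 1.85 ± 0.14. F49E12.10 fell by 2.23 ± 0.39 and the trehalase gene tre-5 fell by 1.32 ± 0.26, and nduo-2 and nduo-4, subunits of the respiratory chain encoded in the mitochondrial genome, fell, at -1.70 ± 0.33 and -1.15 ± 0.25. srw-85, a chemoreceptor gene, fell by 1.83 ± 0.58 (adjusted p = 0.0314), a call lost in 5 alternatives, such as DESeq2 (adjusted p = 0.0648). The other adjusted p ran from 5.50e-10 for ncl-1 to 0.00391 for nduo-4.

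Intestinal lists were not called in elt-7(-), although single members passed: pho-1, an acid phosphatase gene of the intestine, fell by 0.88 ± 0.12 and the proton exchanger gene nhx-2 fell by 0.71 ± 0.15, while act-5 rose by 0.55 ± 0.14 and vha-3 by 1.20 ± 0.08. The lists that passed belong to other tissues and to translation. Of the cuticle collagen genes 22 of 60 tested members rose and 0 fell (25 and 0 adjusted over the list alone). The median was 0.65 (camera adjusted p = 6.39e-09, and adjusted p = 0.934 with an estimated correlation), for example col-107 at 1.04 ± 0.15 and col-103 at 1.05 ± 0.16. Of the body muscle genes 13 of 22 tested members rose and 1 fell (14 and 1 adjusted over the list alone). The median was 0.47 (camera adjusted p = 1.94e-06, and adjusted p = 0.934 with an estimated correlation). They include the giant sarcomere genes unc-89 at 1.29 ± 0.09 and ttn-1 at 1.38 ± 0.11 and the myosin gene unc-54 at 1.14 ± 0.14. Of the ribosomal protein genes 27 of 78 tested members rose and 0 fell (37 and 0 adjusted over the list alone). The median was 0.26 (camera adjusted p = 6.34e-09, and adjusted p = 0.934 with an estimated correlation). They include rps-20 at 0.72 ± 0.14 and rpl-15 at 0.63 ± 0.12. Among endoderm regulators pop-1, the Wnt effector gene, rose by 0.63 ± 0.11.

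In all, 3291 genes were called in elt-7(-), 1439 higher and 1852 lower, and 298 changed at least 2-fold, 175 higher and 123 lower. Without elt-7(-) replicate 3 the count was 1819. Camera called 3 of 32 lists, and 5 without wild-type replicate 2. All elt-7(-) larvae were sorted after the last sort of any other genotype, so the sort period and the genotype cannot be told apart in this contrast. Exons of pho-1 and set-25 overlap another gene.

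The double mutant against wild type gives the loss of both factors. Its largest rises included genes that stayed low in both single mutants, such as Y17G7B.23, clec-74 and abu-10. Y17G7B.23 had 3 reads in wild type and 2613 in the double mutant (ratio 1134, 95% counting interval 388 to 5503). eat-2, a nicotinic receptor subunit gene of pharyngeal muscle, rose by 7.20 ± 0.25 (from 0.445 ± 0.118 to 66.7 ± 13.2 CPM), the C-type lectin gene clec-74 by 6.55 ± 0.24 and ani-2, an anillin gene of the germline, by 6.04 ± 0.19. abu-10, a glutamine- and asparagine-rich protein gene, went from 3 reads to 932 (ratio 404, 95% counting interval 138 to 1965). F10C1.9 fell by 7.71 ± 0.25, the spinster-like transporter gene spin-3 fell by 7.58 ± 0.35, Y66H1A.5 fell by 7.40 ± 0.27, irg-3 fell by 7.32 ± 0.25 and math-3, which encodes a MATH-domain protein, fell by 7.11 ± 0.27, while C52E2.5 kept 1 of 549 reads (ratio 422, 95% counting interval 75.4 to 16680.0). The adjusted p of these genes ran from 1.87e-13 for F10C1.9 to 3.83e-10 for abu-10.

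Intestinal effector genes were low as groups. Of the cathepsins and digestive proteases 3 of 24 tested members rose and 18 fell (3 and 18 adjusted over the list alone). The median was -3.25 (camera adjusted p = 2.34e-05, and adjusted p = 0.173 with an estimated correlation): asp-3 went from 595 ± 128 to 23 ± 4.80 CPM and cpz-2 fell by 6.45 ± 0.15. Of the intestinal transporters 4 of 20 tested members rose and 15 fell (4 and 15 adjusted over the list alone). The median was -1.04 (camera adjusted p = 4.32e-04, and adjusted p = 0.173 with an estimated correlation): vha-6, the proton pump subunit of the apical gut membrane, fell by 6.20 ± 0.21 and haf-9 fell by 5.45 ± 0.18. Of the esterases and phosphatases 3 of 25 tested members rose and 15 fell (3 and 15 adjusted over the list alone). The median was -0.91 (camera adjusted p = 7.42e-04, and adjusted p = 0.0983 with an estimated correlation). They include the lysosomal lipase gene lipl-5 at -5.24 ± 0.24. Of the C-type lectins 18 of 100 tested members rose and 65 fell (18 and 65 adjusted over the list alone). The median was -2.48, or -2.25 with the 10 members at 0 reads in a group set to their bound (camera adjusted p = 2.34e-05, and adjusted p = 0.157 with an estimated correlation). Of the antimicrobial effectors 10 of 37 tested members rose and 22 fell (10 and 23 adjusted over the list alone, camera adjusted p = 0.00328, and adjusted p = 0.301 with an estimated correlation). Examples are spp-14 at -6.35 ± 0.16 and spp-5 at -4.05 ± 0.11. The intermediate filament genes ifd-1, ifb-2 and ifc-1, which line the gut lumen, fell, at -5.53 ± 0.15, -2.25 ± 0.10 and -3.69 ± 0.19, but the brush border list was not called (camera adjusted p = 0.670), as 7 of 16 tested members rose and 6 fell (7 and 6 adjusted over the list alone). Fatty acid synthesis genes were lower, as 0 of 21 tested members rose and 13 fell (0 and 13 adjusted over the list alone, camera adjusted p = 0.00304, and adjusted p = 0.440 with an estimated correlation). An example is the elongase gene elo-5 at -5.14 ± 0.32. Of the nuclear hormone receptors 34 of 209 tested members rose and 93 fell (34 and 93 adjusted over the list alone, camera adjusted p = 0.00877, and adjusted p = 0.427 with an estimated correlation).

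Other tissues again moved with the strain. Of the germline genes 18 of 21 tested members rose and 1 fell (18 and 1 adjusted over the list alone). The median was 3.45 (camera adjusted p = 2.35e-08, and adjusted p = 0.0907 with an estimated correlation). Of the adult and oocyte genes 11 of 12 tested members rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.12e-04, and adjusted p = 0.157 with an estimated correlation), while vit-6 fell by 1.43 ± 0.56. Heat shock genes rose (12 of 13 tested members rose and 0 fell, 12 and 0 adjusted over the list alone, camera adjusted p = 2.49e-04, and adjusted p = 0.0916 with an estimated correlation). Of the body muscle genes 14 of 22 tested members rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00395, and adjusted p = 0.660 with an estimated correlation). Of the pharynx markers 10 of 18 tested members rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0428, and adjusted p = 0.765 with an estimated correlation). Examples are phat-5 at 1.25 ± 0.18 and lys-8, a lysozyme gene also expressed in the intestine, at -1.09 ± 0.19. Of the neuron markers 2 of 28 tested members rose and 21 fell (2 and 21 adjusted over the list alone, camera adjusted p = 4.32e-04, and adjusted p = 0.157 with an estimated correlation). Of the neuropeptide genes 8 of 70 tested members rose and 33 fell (8 and 33 adjusted over the list alone, camera adjusted p = 0.00100, and adjusted p = 0.514 with an estimated correlation).

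In all, 8190 genes were called in the double mutant, 4037 higher and 4153 lower, and 3209 changed at least 2-fold, and camera called 14 of 32 lists. Of the lists that camera called in no contrast, the counts in the double mutant were 1 of 10 higher and 4 lower for GATA and endoderm regulators (1 and 4 adjusted over the list alone), 4 of 31 higher and 12 lower for fatty acid breakdown (3 and 12 adjusted over the list alone), 5 of 18 higher and 9 lower for lipid-binding and yolk-related proteins (5 and 10 adjusted over the list alone) and 12 of 64 higher and 26 lower for cytochrome P450 enzymes (14 and 26 adjusted over the list alone). They were 11 of 60 higher and 27 lower for UDP-glucuronosyltransferases (11 and 27 adjusted over the list alone), 14 of 43 higher and 16 lower for glutathione S-transferases (14 and 16 adjusted over the list alone) and 1 of 18 higher and 4 lower for hypodermis and cuticle markers (1 and 3 adjusted over the list alone). For the remaining lists they were 4 of 12 higher and 5 lower for coelomocyte and excretory markers (4 and 5 adjusted over the list alone), 5 of 12 higher and 1 lower for sperm proteins (4 and 0 adjusted over the list alone) and 2 of 3 higher and 1 lower for genes on the array (2 and 1 adjusted over the list alone). The coelomocyte genes unc-122, lgc-26 and cup-4 rose by 2.34 ± 0.16, 2.56 ± 0.16 and 1.97 ± 0.16. Named genes with exons that overlap another gene were cpz-2, elo-5, lys-8 and math-3.

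How much of the double-mutant change was already present without ELT-2 alone was measured by overlap and by size. Of 4153 genes lower in the double mutant, 3085 (74.3%) were also lower in elt-2(-), where independent lists would share 1305. Simulated unchanged groups that share the wild-type controls gave at most 0 shared calls over 20 simulations (edgeR, as for the data). At most 1 gene was called there in elt-2(-) and 0 in the double mutant, so the calls could not overlap. At an unadjusted p under 0.05 the simulated contrasts shared a median of 50 genes, where independent lists would share 8.55. With the wild-type libraries split between the contrasts the overlap was 2434 to 2580. Of 4037 genes higher in the double mutant, 2978 (73.8%) were also higher in elt-2(-). Over the 3209 genes changed at least 2-fold in the double mutant, the median ratio of the log2 change in elt-2(-) to that in the double mutant was 0.770, and for elt-7(-) it was 0.101. For elt-2(-), pho-11 (-6.14 ± 0.18 against -6.75 ± 0.22) and irg-3 are examples above the median. With split controls the median ratios were 0.668 to 0.741 for elt-2(-) and 0.0637 to 0.106 for elt-7(-). Genes that fell in the double mutant without falling in elt-2(-) form a further group, and 732 of them were lower in the double mutant than in elt-2(-). In the other direction 646 genes were higher in the double mutant, not higher in elt-2(-), and higher in the double mutant than in elt-2(-), and 90 were higher in the double mutant but lower in elt-2(-). Both groups were defined by their elt-2(-) values and then compared with the same libraries, which favours such calls. Among the 732 were asp-3, ifc-1 and ifb-2, which stood at 815 ± 68.3, 294 ± 26.6 and 891 ± 29.8 CPM in elt-2(-) and 23 ± 4.80, 11.3 ± 3.80 and 125 ± 7.40 in the double mutant. Genes lower in the double mutant but higher in elt-2(-) numbered 292 and overlap the 732, and the 90 genes were not set apart from the 646 either. Of the 292, pho-1 went from 18.2 ± 2.17 CPM in wild type to 178 ± 11.2 in elt-2(-) and 0.906 ± 0.0186 in the double mutant.

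**Figure D3:**
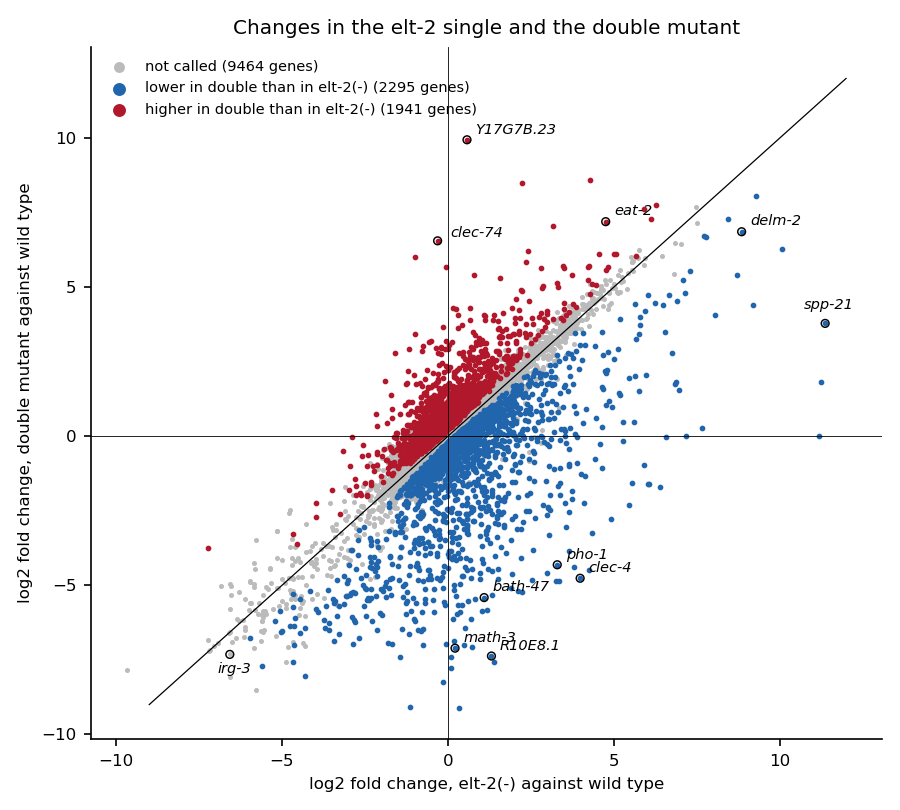
Log2 fold change of each of 13700 genes in elt-2(-) (x axis) and in the double mutant (y axis), both against wild type, with genes called between the double mutant and elt-2(-) coloured (1941 higher, 2295 lower) and named genes circled. Fitted values of genes at or near 0 reads, such as spp-21, F16G10.6 and Y17G7B.23, depend on the prior count.

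Loss of ELT-7 in animals that already lack ELT-2 was read from the double mutant against elt-2(-), where many transcripts that elt-2(-) kept or had raised were low. F16G10.7 went from 1272 reads in elt-2(-) to 0 in the double mutant, at least 307-fold lower. pho-1 fell by 7.61 ± 0.17 (adjusted p = 7.63e-15), clec-4 fell by 8.75 ± 0.42, ech-9, an enoyl-CoA hydratase gene of fatty acid breakdown, fell by 8.74 ± 0.44, and the F-box gene fbxa-182 fell by 8.07 ± 0.31. cpr-4, a cathepsin B gene, stood at 76.6 ± 20.4 CPM in wild type, 960.1 ± 94.2 in elt-2(-) and 5.45 ± 3.64 in the double mutant. A smaller set went up: Y17G7B.23 rose by 9.37 ± 0.34, and the lectin gene clec-74 rose by 6.86 ± 0.24.

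Brush border and vacuolar pump genes were called lower here. The elt-2(-) libraries also enter the contrast in which both lists were called higher, so a rise in elt-2(-) alone gives opposite calls. In the double mutant against wild type neither was called, with medians of 0.10 (camera adjusted p = 0.670) and -0.03 (camera adjusted p = 0.670). Of the brush border genes 0 of 16 tested members rose and 11 fell (1 and 11 adjusted over the list alone). The median was -0.56 (camera adjusted p = 1.57e-06, and adjusted p = 0.284 with an estimated correlation), led by ifd-1 at -6.13 ± 0.15 and ifc-1 at -4.71 ± 0.20. Of the intestinal transporters 1 of 20 tested members rose and 14 fell (1 and 15 adjusted over the list alone). The median was -0.97 (camera adjusted p = 3.77e-08, and adjusted p = 0.105 with an estimated correlation). Examples are pept-1 at -3.87 ± 0.15, vha-6 at -5.22 ± 0.21 and nhx-2 at -3.71 ± 0.16. Of the vacuolar pump genes 1 of 20 tested members rose and 16 fell (2 and 16 adjusted over the list alone, camera adjusted p = 9.07e-07, and adjusted p = 0.214 with an estimated correlation). Of the C-type lectins 12 of 100 tested members rose and 55 fell (13 and 56 adjusted over the list alone). The median was -2.005, or -1.97 with 9 members at 0 reads set to their bound (camera adjusted p = 3.77e-08, and adjusted p = 0.110 with an estimated correlation). Of the digestive proteases 3 of 24 tested members rose and 12 fell (3 and 13 adjusted over the list alone, camera adjusted p = 2.86e-05, and adjusted p = 0.247 with an estimated correlation). Of the antimicrobial effectors 7 of 37 tested members rose and 19 fell (7 and 19 adjusted over the list alone, camera adjusted p = 0.00178, and adjusted p = 0.304 with an estimated correlation). Of the esterases and phosphatases 1 of 25 tested members rose and 10 fell (2 and 11 adjusted over the list alone, camera adjusted p = 0.00615, and adjusted p = 0.145 with an estimated correlation). Metal-handling genes were lower, as 1 of 18 tested members rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.0165, and adjusted p = 0.338 with an estimated correlation). Examples are the ferritin gene ftn-1 at -3.14 ± 0.25 and the heme transporter gene hrg-1 at -2.90 ± 0.31. Fatty acid synthesis genes (0 of 21 tested members rose and 10 fell, 0 and 10 adjusted over the list alone, camera adjusted p = 0.00178, and adjusted p = 0.383 with an estimated correlation) and nuclear hormone receptors (12 of 209 tested members rose and 47 fell, 12 and 46 adjusted over the list alone, camera adjusted p = 0.0467, and adjusted p = 0.460 with an estimated correlation) were also called lower.

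Other lists were called higher in the double mutant than in elt-2(-). Of the neuropeptide genes 32 of 70 tested members rose and 4 fell (41 and 4 adjusted over the list alone). The median was 0.38 (camera adjusted p = 2.81e-06, and adjusted p = 0.338 with an estimated correlation). They include flp-6 at 0.96 ± 0.17. Of the neuron markers 8 of 28 tested members rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.0436, and adjusted p = 0.383 with an estimated correlation). Of the collagens 17 of 60 tested members rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.525 with an estimated correlation). Of the insulin-like peptides 7 of 22 tested members rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0214, and adjusted p = 0.383 with an estimated correlation). Of the cell cycle and histone genes 7 of 29 tested members rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00550, and adjusted p = 0.460 with an estimated correlation). The elt-2(-) libraries, which enter this contrast, had medians under wild type for all of these lists but the cell cycle genes, so low values in elt-2(-) alone give such calls. In the double mutant against wild type neuropeptide genes and neuron markers were still called lower, with medians of -0.34 and -0.42. Collagens (camera adjusted p = 0.784), insulin-like peptides (camera adjusted p = 0.997) and cell cycle genes (camera adjusted p = 0.0818) were not called there. In the germline list 1 of 21 tested members rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.277). elt-3 rose by 0.78 ± 0.13 and elt-2 reads fell by 1.36 ± 0.22 (adjusted p = 1.59e-04). In all, 4236 genes were called, 1941 higher and 2295 lower, 1403 of them at least 2-fold, and 15 of 32 lists. Genes lower in elt-7(-) against wild type and lower in the double mutant against elt-2(-) numbered 525, where independent lists would share 310, and these contrasts share no libraries. Exons of pho-1 overlap another gene.

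Loss of ELT-2 in animals that lack ELT-7 was read from the double mutant against elt-7(-). spp-8, a saposin-like gene, fell by 6.83 ± 0.40, irg-3 fell by 7.15 ± 0.25 and pho-11 fell by 6.73 ± 0.22, while nas-5, an astacin protease gene, rose by 6.49 ± 0.26 and eat-2 by 6.78 ± 0.28. Of the digestive proteases 3 of 24 tested members rose and 18 fell (3 and 18 adjusted over the list alone, camera adjusted p = 6.32e-07, and adjusted p = 0.124 with an estimated correlation). Of the C-type lectins 14 of 100 tested members rose and 69 fell (14 and 69 adjusted over the list alone). The median was -2.50, or -2.24 with 9 members at 0 reads set to their bound (camera adjusted p = 6.32e-07, and adjusted p = 0.124 with an estimated correlation). Of the germline genes 16 of 21 tested members rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 9.53e-08, and adjusted p = 0.124 with an estimated correlation). Collagens were called lower here (1 of 60 tested members rose and 27 fell, 1 and 23 adjusted over the list alone, camera adjusted p = 5.83e-04, and adjusted p = 0.407 with an estimated correlation), and so were the fasting and DAF-16 target genes (3 of 17 tested members rose and 10 fell, 3 and 10 adjusted over the list alone, camera adjusted p = 0.00767, and adjusted p = 0.130 with an estimated correlation). The elt-7(-) libraries also enter the contrast in which collagens were called higher. In the double mutant against wild type the collagen median was -0.06 and the list was not called (camera adjusted p = 0.784). In elt-2(-) the collagen median lay under wild type, and the list was not called there either. These values do not decide whether loss of ELT-2 lowers collagens. Camera called 14 lists in all, and their adjusted p with an estimated correlation ran from 0.124 to 0.694. The genes called numbered 7303, 3693 higher and 3610 lower, and the elt-7(-) sorts were again later than all others. Exons of pho-11 overlap another gene.

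Whether the single-mutant changes add up to the double-mutant change was tested as an interaction on the log2 scale, the change in the double mutant against elt-7(-) less the change in elt-2(-) against wild type. It uses the elt-7(-) libraries, all sorted later than the other groups, so it carries any effect of the sort period. The 10 genes with the smallest p were all lower in the double mutant than the sum predicts. The interaction of pho-1 was -6.72 ± 0.21, that of ifd-1, an intermediate filament gene of the gut, -5.83 ± 0.18, that of gtl-1, a TRPM channel gene of the intestine, -4.25 ± 0.16, and that of inx-16, an intestinal gap junction gene, -2.72 ± 0.10. F57F4.4, bath-47, T06A1.5, Y105C5A.24, Y82E9BR.21 and C18B2.5 ranged from -4.24 ± 0.17 to -7.47 ± 0.28. Mean CPM of ifd-1 was 53.7 ± 3.32 in wild type, 43.5 ± 5.88 in elt-7(-), 81.6 ± 4.45 in elt-2(-) and 1.14 ± 0.264 in the double mutant, and that of gtl-1 was 156 ± 13.9, 139 ± 16.8, 123 ± 7.37 and 5.73 ± 0.774. The adjusted p of the 10 genes ran from 1.14e-12 to 1.06e-11. Interactions of the regulators elt-2, elt-3 and elt-7 were -1.25 ± 0.28, 0.92 ± 0.19 and -0.82 ± 0.18. Because elt-2 and elt-7 are the mutated genes, their values compare reads left by mutant alleles, or by the array for elt-2, with reads of intact genes. They cannot be read as regulation of either gene.

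The lists with negative interactions were mostly those of intestinal function. Of the brush border genes, 11 of 16 had a negative interaction and 0 a positive one (13 and 0 adjusted over the list alone). The median was -0.56 (camera adjusted p = 2.29e-09, and adjusted p = 0.150 with an estimated correlation). For the transporters the counts were 12 of 20 and 0 (13 and 0 adjusted over the list alone; camera adjusted p = 1.12e-08, and adjusted p = 0.0775 with an estimated correlation). Examples are pept-1 at -3.57 ± 0.19 and vha-6 at -5.44 ± 0.25. For the C-type lectins, 53 of 100 were negative and 8 were positive (54 and 10 adjusted over the list alone; camera adjusted p = 8.27e-10, and adjusted p = 0.0775 with an estimated correlation). For the digestive proteases they were 13 of 24 and 0, also 13 and 0 adjusted over the list alone (camera adjusted p = 1.15e-06, and adjusted p = 0.150 with an estimated correlation). Examples are asp-3 at -5.38 ± 0.23 and cpr-4 at -7.18 ± 0.45. The vacuolar pump (camera adjusted p = 1.33e-06, and adjusted p = 0.157 with an estimated correlation), antimicrobial (camera adjusted p = 0.00279, and adjusted p = 0.327 with an estimated correlation), esterase and phosphatase (camera adjusted p = 0.00639, and adjusted p = 0.150 with an estimated correlation), fatty acid synthesis (camera adjusted p = 0.00211, and adjusted p = 0.511 with an estimated correlation), ribosomal protein (camera adjusted p = 1.72e-06, and adjusted p = 0.715 with an estimated correlation) and fasting target (camera adjusted p = 0.0498, and adjusted p = 0.266 with an estimated correlation) lists were negative too. For ribosomal proteins the call rests on elt-7(-), where the median was 0.26, as it was -0.05 in the double mutant against elt-2(-) (camera adjusted p = 0.232). The fasting target list was not called in the double mutant against elt-2(-) either (camera adjusted p = 0.221). Neuropeptide genes had a positive interaction (camera adjusted p = 5.02e-04, and adjusted p = 0.579 with an estimated correlation), with 16 of 70 positive and 2 negative in both adjustments. In all, 3343 genes had an interaction, 1500 positive and 1843 negative, and 1387 of at least 1 log2 unit. Of 4230 genes higher in elt-2(-) than in wild type, 1315 were lower in the double mutant than in elt-2(-), and 852 of these were not above wild type in the double mutant. In the other direction, of 4304 genes lower in elt-2(-), 793 were higher in the double mutant than in elt-2(-), and 561 of these were not below wild type. The elt-2(-) libraries enter both contrasts, which favours such reversals in either direction.

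**Figure D4:**
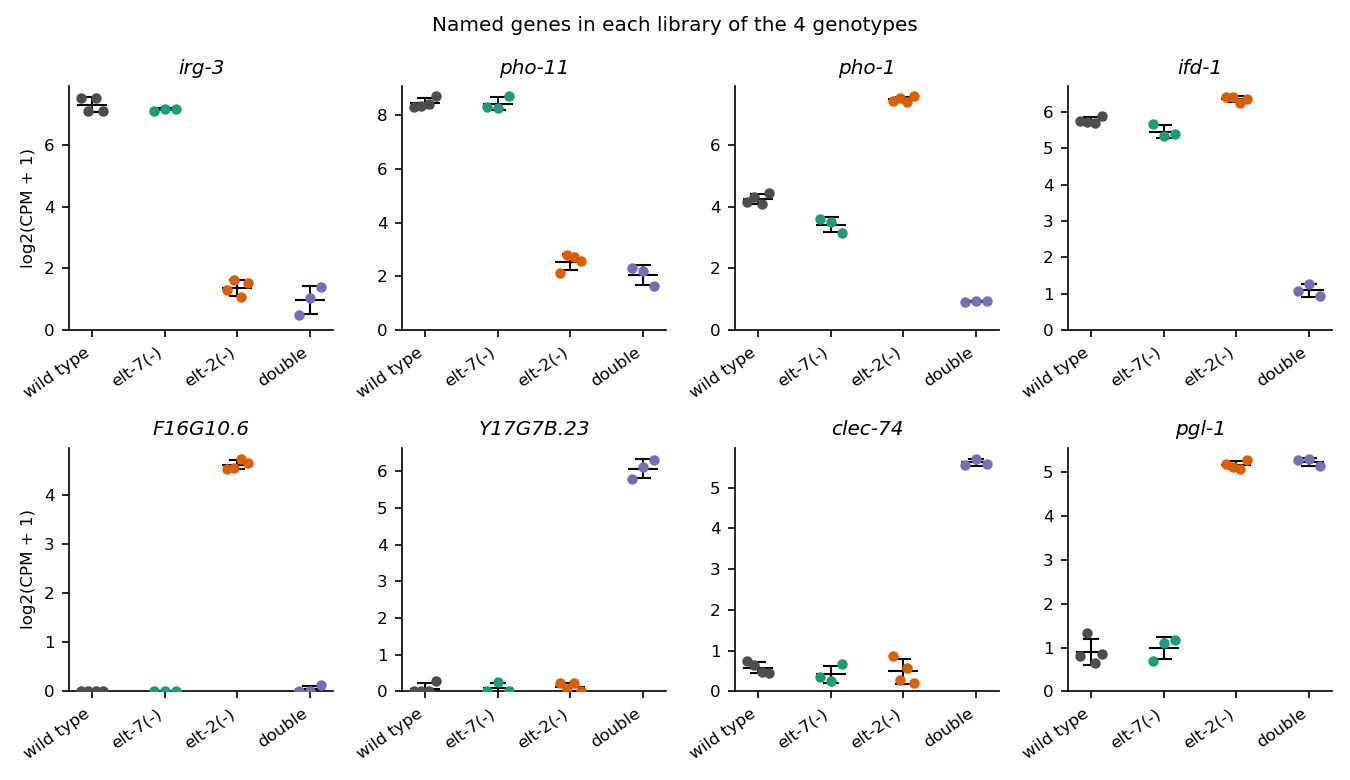
Log2(CPM + 1) of irg-3, pho-11, pho-1, ifd-1, F16G10.6, Y17G7B.23, clec-74 and pgl-1 in each library (points), with the group mean and SD of the plotted values (bars), for the 4 genotypes. irg-3 and pho-11 are low in both mutants without ELT-2, and pgl-1 is high in both. pho-1 and ifd-1 are lowest in the double mutant, and pho-1 is also lower in elt-7(-) than in wild type.

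**Figure D5:**
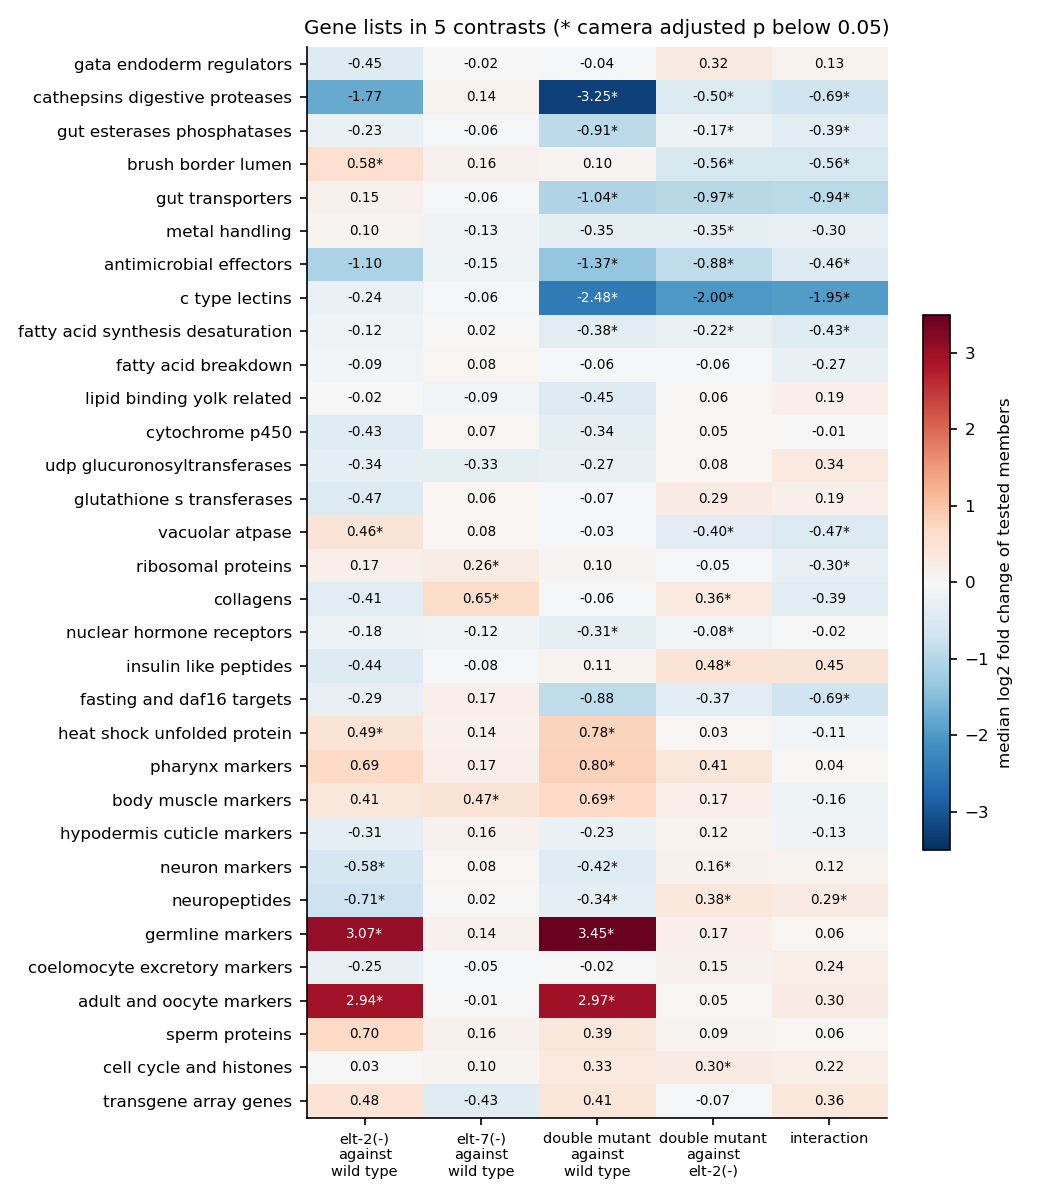
Median log2 change of the tested members of each of 32 gene lists in 5 contrasts (colour and number), with a star where the camera adjusted p with the preset correlation of 0.01 was under 0.05. No starred call held with an estimated correlation, and the collagen and muscle lists are starred in elt-7(-) where no intestinal list is.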

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

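All tests of explanations reported in this part were chosen after the result was seen. The total of elt-2(-) replicate 2, 19071067 counts, lay far above the other 3 libraries of its group; 14 sets of 4 values were tested in this way, 1 stood out, and chance picks about 1 in 20. The interaction, a test of whether loss of ELT-2 acts alike with and without ELT-7, called 3343 genes and 11 gene lists. It uses the later-sorted elt-7(-) libraries. Its values were -6.37 for F57F4.4, -5.825 for ifd-1, -6.72 for pho-1, -4.25 for gtl-1, -7.02 for bath-47, -7.47 for T06A1.5, -4.46 for Y105C5A.24, -2.72 for inx-16, -5.02 for Y82E9BR.21 and -4.24 for C18B2.5. For the regulators it was -1.255 for elt-2, 0.92 for elt-3 and -0.82 for elt-7. The values of elt-2 and elt-7, the mutated genes, include remaining reads of mutant alleles and cannot be read as regulation.

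Other splits of the same libraries were counted for each number of called genes. In elt-2(-) against wild type 1 of 35 splits, the real split with 8534 genes, reached that count, and the highest other split gave 0. The real split was also the 1 of 35 in elt-7(-) (3291 against 777), in the double mutant against wild type (8190 against 4192) and in the double mutant against elt-2(-) (4236 against 295), and 1 of 100 drawn for the interaction (3343 against 1908). These shares argue against chance for the 5 counts but do not exclude it. A share of 1 in 35 is the smallest those splits allow, and no share was adjusted over the contrasts. Splits that mix genotypes also widen the spread within groups, which lowers their counts. The interaction splits exchanged libraries between wild type and elt-7(-) and between elt-2(-) and the double mutant. They therefore bear on any difference by elt-7, not on the interaction alone. The double mutant against elt-7(-) allows 10 splits, too few for a share under 0.05; the real split gave 7303 genes and the highest other 0. The split with 4192 genes sets 3 wild-type libraries against a group of the remaining wild-type library and the 3 double-mutant libraries, which still parts the genotypes in large measure.

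Germline and oocyte transcripts were higher in both strains without ELT-2. Carry-over of adult animals is argued against only weakly, because the yolk gene vit-6 changed by -1.234 on the log2 scale in elt-2(-) (standard error 0.50, adjusted p = 0.0408). Yolk and eggshell genes summed to 0.873 CPM there against 1.83 CPM in wild type. Most of both sums was vit-6 itself (0.664 and 1.51 CPM), so they add little to that single low gene. Eggs or unhatched embryos may contribute, since the median of the oocyte genes other than yolk and eggshell genes was 3.015 with 10 of 11 higher, and neither this value nor any other here separates maternal from larval transcripts. An effect of ELT-2 loss whatever the state of ELT-7 also stays open: the germline median was 3.554 in the double mutant against elt-7(-). The array strain and the selection of GFP-negative larvae go with the state of elt-2 in every library, so these cannot be told apart; larvae of all genotypes went through the sorter.

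Reads of elt-2 remained in both elt-2 mutants, at 22.8% of wild type in elt-2(-). Array-bearing larvae with elt-2 at the wild-type level are argued against as the source, because 34 of 3501 abundant genes (at least 50 CPM in wild type) kept less than the 17.7% that elt-2 kept in its lowest library, in every elt-2(-) library. A single source of elt-2 and rol-6 reads with the same ratio in both strains is argued against too. The ratio was 2.804 times higher in elt-2(-) (0.819 to 1.10) than in the double mutant (0.164 to 0.527), with no overlap. The strains also differ in elt-7, so an array source whose ratio differs between them stays open. A few larvae with many array copies may still contribute, since the 10 named genes with the largest falls kept a median of 1.227% of wild type (0.971% to 1.43%), and reads from the parts of elt-2 left by the allele, which the labels do not describe, are open as well.

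The 175 genes at least 2-fold higher in elt-7(-) are the remaining pattern. If they answered to ELT-7 whatever the state of ELT-2, they would rise as much in the double mutant against elt-2(-). Their median there was 0.2385 (upper quartile 0.566, against a lower quartile of 1.12 in elt-7(-)), with 34 called higher and 13 lower. Over all 13700 genes, 1941 were called higher and 2295 lower in that contrast. The 175 genes were chosen for a rise of at least 2-fold in elt-7(-), which favours smaller values in another contrast. The comparison therefore does not decide that reading. Taking out a trend with exon length moved no tested gene by more than 0.808 log2 units. Such a trend therefore does not account for the whole of any of these rises of at least 2-fold. After this correction 173 of them stayed called higher, which so small a shift made likely beforehand. Whether gene length adds to part of the rises is not decided by that count. The sort period may be the cause: 28 days lay between the last sort of any other genotype and the first elt-7(-) sort, and no other genotype was sorted in that period. The sort period cannot be told apart from an effect of ELT-7, whether or not that effect needs ELT-2.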

How the results depend on the processing

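The limma-trend alternative on the deposited log2 values was chosen after the data were seen; the other alternatives were fixed before. All 6 gene counts and the overlap stayed within 1.5 times their values under DESeq2, limma-voom, RLE and upper-quartile scaling, both filters, the replicate block, contrast-only fits and limma-trend, where each could be run. With a 2-fold minimum the counts were 2908 (elt-2(-)), 298 (elt-7(-)), 3209 (double mutant), 1403 (double mutant against elt-2(-)), 2879 (double mutant against elt-7(-)) and 1387 (interaction), and the overlap 941. At an adjusted p under 0.01 they were 1524 in elt-7(-), 2696 in the double mutant against elt-2(-) and 1889 for the interaction. Leaving out each library gave 1819 (without elt-7(-) replicate 3) to 4367 (without double-mutant replicate 3) genes in elt-7(-). The median share of elt-2(-) was 0.726 with a minimum mean of 5 CPM, 0.830 with no minimum change, 0.714, 0.741, 0.731, 0.678, 0.668 and 0.698 with split controls, and 0.736 to 0.780 leaving out each library. The share of elt-7(-) was 0.176 with no minimum change and 0.0637 in 1 split assignment. Gene lists called with an estimated correlation numbered 0 in all 6 contrasts. The self-contained fry test called 20 in elt-2(-), 24 in the double mutant and 24 in the double mutant against elt-7(-). Leaving out libraries gave 7 to 12 lists in elt-2(-) and 3 to 5 in elt-7(-). The cause of these shifts was not tested beyond what the stricter thresholds do by construction.

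The labels number replicates alike in each group. Same-numbered libraries of different groups had correlations of their deviations of -0.127 to 0.248 (median 0.029, 3 of 19 above 0.1). Pairs with other numbers had -0.166 to 0.175 (median -0.003, 4 of 54 above 0.1). Of 14 libraries, 7 correlated best with their own number, so a weak pairing by number cannot be excluded. With the replicate block the counts were 8570, 3020, 7986, 4063, 7331 and 3336 genes in the order above, the overlap 3024, the shares 0.763 and 0.0989, and the lists 12 in elt-2(-). Among 16556 recomputed values of all 828 named results (a gene in a contrast, list members and regulators included), 16204 kept direction and side of the threshold, 349 in 84 results were weaker, 3 were stronger and 0 reversed. For the 110 results named by size or p, 2195 of 2200 were kept, and the 5 lost calls were all of srw-85 in elt-7(-). In the simulation 1.5-fold changes were recovered for 50% of genes in elt-7(-). Far fewer genes changed there than the 3291 called in the data, which makes the adjusted threshold stricter in the simulation. That share therefore does not carry over, and how complete calls of that size are in the data is not known.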

Other observations

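Families and chromosome windows in this part were searched after the results were seen, over 157 gene families and 204 windows of 0.5 Mb. Fisher's exact test was 1-sided, for more members than expected, and was adjusted over all families or windows and 8 sets of genes. Members of a family and neighbours are not independent, and the counting could split reads between near-identical members. Genes with BTB and MATH domains, which serve as substrate adaptors of ubiquitin ligases, stood out in elt-2(-): 18 of 32 tested bath genes were at least 4-fold higher than in wild type, where 1.74 were expected (adjusted p = 9.98e-13), and 17 were in the double mutant (adjusted p = 9.60e-12). bath-7 had a log2 change of 4.86 in elt-2(-) and 4.79 in the double mutant, and bath-1 of 3.76 and 3.69. In another contrast, 14 of 23 math genes were at least 4-fold lower in the double mutant than in elt-2(-) (0.885 expected, adjusted p = 1.96e-12), and 5 of 23 were at least 4-fold lower in elt-2(-) than in wild type (adjusted p = 0.0111). In the double mutant against elt-2(-), math-27 was at -5.59 and math-42 at -3.46, the latter 2.58 in elt-2(-) against wild type. On chromosome II, 26 of 58 tested genes between 1500001 and 2000000 were at least 4-fold lower in the double mutant than in elt-2(-) (2.23 expected, adjusted p = 5.11e-19). Of the 14 math genes, 11 lie in this window, as do 16 of all 23 tested math genes and 6 of 32 bath genes, so the family and the window are not separate findings.

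C-type lectins split by genotype: 22 of 100 were at least 4-fold higher and 21 at least 4-fold lower in elt-2(-), and 49 were at least 4-fold lower in the double mutant than in elt-2(-) (3.85 expected, adjusted p = 5.31e-40). F-box genes of the fbxa family had 23 of 117 members at least 4-fold higher in elt-2(-) (adjusted p = 5.26e-06) and 15 at least 4-fold lower in the double mutant than in elt-2(-) (adjusted p = 2.90e-03). In elt-7(-), 5 of 8 linker histone genes (hil) were at least 2-fold higher than in wild type (0.102 expected, adjusted p = 1.57e-06), among them hil-2 at 1.10 and hil-3 at 1.11 on the log2 scale, chosen here after their values were seen. The same genes had changes of 0.31 and 0.39 in the double mutant against elt-2(-), which missed the threshold. Of 12 mitochondrial genes, 4 were at least 4-fold lower in elt-2(-) (adjusted p = 9.49e-03) and 3 at least 2-fold lower in elt-7(-) (adjusted p = 8.85e-03).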
